A study of Mus musculus with 10 samples.

How the data were processed

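RNA-seq libraries of in vitro differentiated mouse myotubes (2 days of differentiation) came from 3 groups of 2, GAP-scr, GAP-2 and GAP-2/3, and ChIRP-seq libraries from 1 even-probe pull-down, 1 odd-probe pull-down, 1 input and 1 LacZ-probe control. Per the labels' protocols, polyadenylated RNA was prepared with a TruSeq stranded mRNA kit and the ChIRP DNA with a NuGEN low-input kit. The submitters' processing notes name CASAVA, FastQC, Bowtie2, TopHat2, Cufflinks, Cuffdiff, Trimmomatic, cutadapt, MACS and bedtools and the build mm9, without roles, order or versions.

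Expression was deposited by the authors as FPKM, a fragment number scaled to transcript length and to the mapped fragments of the library, in 1 table of 11228 genes with a column per library. The lowest maximum of a gene over the libraries is 1.03 FPKM and no value is exactly 0; the filter behind this is not given in the sources used here. Read counts were not recovered from these values, so depth and counting error are unknown and no count model was used. Charme is not analysed here. The authors' peak file gives 798 merged peaks with a score each, deposited without a header. The score was used only to describe and rank peaks within the list.

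FPKM values were taken as log2(FPKM + 1), with no further scaling, for the 10993 genes with a mean of at least 1 FPKM over the 6 libraries (235 were below it). The 3 groups were fitted together with limma 3.58.1 in R 4.3.3, with an intensity trend and no covariate, so that they share one estimate of the spread, and contrasts were taken for each arm against GAP-scr, for the mean of both arms against GAP-scr and for GAP-2/3 against GAP-2. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Fold changes and their SE are on the log2(FPKM + 1) scale.

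The gene lists, 28 in all, from muscle structure to stress responses and markers of other cells, and the rule for the genes named were fixed before the data were examined, and 25 lists had the 5 tested members that a test required. They were tested with limma's camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01, and the p-values were adjusted over the 25 lists. No list was past the threshold in any contrast when the correlation was estimated from the residuals. The macrophage list had 2 tested members, the adipocyte list 3 and the endothelial list 0, and these were not tested.

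The rule for named genes was as follows: for each arm against GAP-scr and for the arms against each other, the 5 highest and 5 lowest log2 changes among genes past the threshold with a mean of at least 5 FPKM and no overlap between the libraries compared; for the mean of both arms the 12 highest and 12 lowest; from each list up to 4 members with the smallest p in the mean of both arms; and, for the peaks, the 10 with the highest score (13 were tied and are all counted) and up to 10 changed genes under a peak. Overlap and correlation between the arms were set beside 100 simulations of unchanged arms against the same controls, in which each gene was drawn independently.

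Peak positions are given as 1-based GRCm38 coordinates. The build was inferred from the positions, since the notes name mm9 and 1 peak lies beyond the end of chromosome X in mm9, a length known in general and held in no file used here. No genome sequence was used and no table of chromosome lengths, so the end of the last RefSeq gene stands for the length of a chromosome, a choice made after the peaks were seen. Of the tested genes 10950 (99.6%) matched a RefSeq gene of GRCm38.p6, 10266 by symbol and 684 by an older symbol. Genes whose span overlapped a peak by at least 1 bp were compared with changed genes by a two-sided Fisher's exact test in scipy 1.17.1 with Python 3.11.15.

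The limma and camera steps were tested on simulated data, with 200 of 10993 genes changed in both arms. For the mean of both arms, 100% of genes changed by a log2 of 1 and 74% of those changed by 0.5 were recovered, with 13 unchanged genes called, and for GAP-2 alone 100% and 53%, with 14. A simulated list of 40 lower genes passed, and 0 of 20 random lists did. Genes were drawn independently in these data, so lists of correlated genes were not tried. Alternatives were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, quantile normalization, scaling to one median, no intensity trend, the replicate letter as a block, each library left out, a threshold of 0.1, only the libraries of the groups compared, other list tests and other definitions of a gene under a peak. Leaving out both libraries with the most Rn45s and splitting the peak comparison by direction, with logistic models for the lower genes (statsmodels 0.14.6), were added after the data were seen. Count-based tests were planned only for whole reads and were not run.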

Results

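The series examined Charme, a long non-coding RNA of muscle, in mouse myotubes, the multinucleate cells that form when myoblasts fuse, after 2 days of differentiation in culture. Charme was knocked down with gapmers, antisense oligonucleotides that direct RNase H to a transcript, and polyadenylated RNA was sequenced from 2 libraries treated with GAP-2, 2 treated with the set named GAP-2/3 and 2 treated with the scrambled control GAP-scr. A second assay, ChIRP-seq, pulled down Charme with tiling DNA probes and sequenced the DNA that came with it. It comprised an even and an odd probe set, input DNA and a LacZ probe control, with 1 library each.

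The expression table listed 11228 genes in FPKM, of which 10993 reached the mean of 1 FPKM set for testing. The sequencing depth is unknown, since FPKM values do not retain it. Median FPKM ran from 11.9 (GAP-scr replicate B) to 13.3 (GAP-2/3 replicate B). The replicates of a group correlated across genes at 0.989 for GAP-scr, 0.995 for GAP-2 and 0.994 for GAP-2/3 on the log2(FPKM + 1) scale. The first principal component held 57.7% of the variance, with GAP-scr at -24.1 and -23.5, GAP-2 at -1.70 and 3.43, and GAP-2/3 at 25.1 and 20.8. The level of Rn45s, the ribosomal RNA precursor, was uneven: 3387 FPKM in GAP-scr replicate A and 4090 in GAP-2 replicate A, against 93.2 to 176 in the other 4 libraries. The series text calls the 2 libraries of a group biological replicates without saying whether they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

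Charme itself, the target of the knock-down, is not analysed here. The extent of the knock-down in each library was therefore not measured, and the groups rest on the labels alone. All fold changes below are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes.

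The first question was what changed when both gapmer treatments were set against GAP-scr. Transcripts of the contractile apparatus fell. Skeletal α-actin, Acta1, went from 5979 ± 486 FPKM in GAP-scr to 2904 ± 98.8 in GAP-2 and 3071 ± 203 in GAP-2/3 (SD, n = 2 each), log2 changes of -1.04 ± 0.12 and -0.96 ± 0.12 (SE). Its mean over both arms passed at an adjusted p of 6.53e-05 (limma). Over both arms cardiac α-actin, Actc1, which developing skeletal muscle also expresses, fell by 0.88 ± 0.10, the Z-disc protein Actn2 by 1.23 ± 0.12 and nebulin, Neb, by 1.02 ± 0.14. Of the 56 tested members of the sarcomere list 37 were lower and 2 higher (40 and 2 adjusted over the list alone), and its median log2 change was -0.45, or -0.55 relative to the median of all genes. The list was past the threshold in camera (adjusted p = 4.95e-17) but had adjusted p = 0.102 with an estimated correlation. Nebl, which encodes nebulette, went the other way, from 1.12 ± 0.353 to 3.52 ± 0.132 and 4.29 ± 0.307 FPKM.

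**Figure D1:**
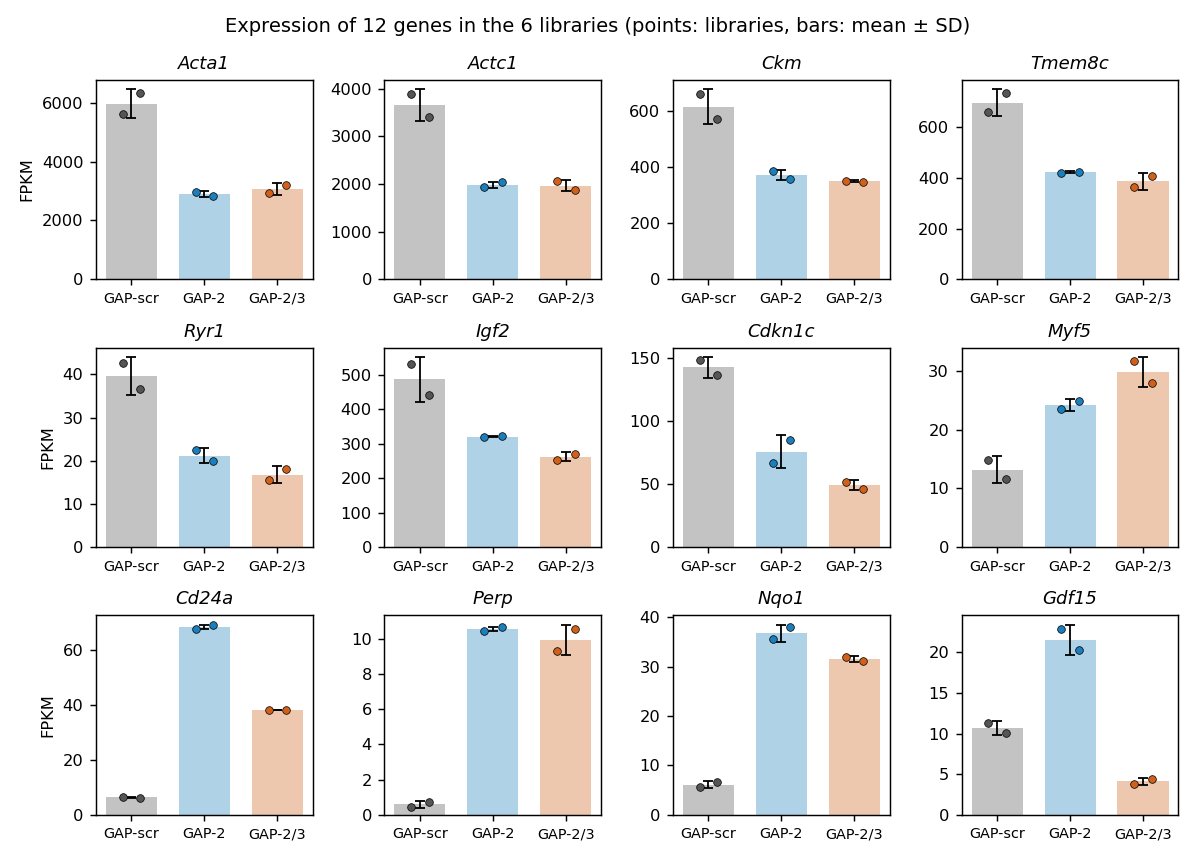
FPKM of 12 genes in GAP-scr, GAP-2 and GAP-2/3, where points are the 2 libraries of a group and bars the mean with its SD. The muscle genes Acta1, Actc1, Ckm, Tmem8c and Ryr1 were lower in all 4 gapmer libraries than in both GAP-scr libraries, Myf5, Cd24a, Perp and Nqo1 were higher, and Gdf15 was higher in GAP-2 and lower in GAP-2/3.

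Genes that couple excitation to contraction moved alike. Of 28 tested, 20 were lower and 1 higher (22 and 2 adjusted over the list alone; camera adjusted p = 3.25e-12, and adjusted p = 0.102 with an estimated correlation). They included Ryr1, the calcium release channel of the sarcoplasmic reticulum (-1.03 ± 0.11), Cacna1s, the pore of its voltage sensor (-0.87 ± 0.10), and Chrng, the fetal subunit of the acetylcholine receptor, at 397 ± 5.85 FPKM in GAP-scr and 215 ± 1.46 and 216 ± 4.06 in the gapmer arms. In the list of muscle energy metabolism 11 of 22 members were lower and 2 higher (12 and 2 adjusted over the list alone; camera adjusted p = 1.66e-05, and adjusted p = 0.12 with an estimated correlation). Muscle creatine kinase, Ckm, fell by 0.77 ± 0.10, whereas Pdk4, a kinase that restrains pyruvate oxidation, rose by 1.03 ± 0.10.

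Among 15 myogenic transcription factors 7 were lower and 3 higher (7 and 3 adjusted over the list alone; camera adjusted p = 0.00502, and adjusted p = 0.19 with an estimated correlation). Without both libraries highest in Rn45s, a fit added after the data were seen, this list did not pass. Myod1 went from 140 ± 17.1 FPKM to 95.7 ± 8.70 in GAP-2 and 91.7 ± 0.982 in GAP-2/3. Myf5, a factor of undifferentiated myoblasts, rose from 13.2 ± 2.27 to 24.2 ± 1.07 and 29.8 ± 2.58. Of 21 genes of fusion and adhesion 6 were lower and 4 higher, or 7 and 1 under either scaling (6 and 4 adjusted over the list alone; camera adjusted p = 0.00563, and adjusted p = 0.324 with an estimated correlation). The lower ones included Tmem8c, the fusion protein myomaker, at 697 ± 52.6 FPKM in GAP-scr against 422 ± 2.95 and 385 ± 31.8.

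A further list held genes of the Igf2-H19-Tnnt3 region of chromosome 7. Of 20 tested, 8 were lower and none higher (9 and 0 adjusted over the list alone; camera adjusted p = 4.05e-06, and adjusted p = 0.166 with an estimated correlation). Cdkn1c, an inhibitor of cyclin-dependent kinases, fell by 1.22 ± 0.11, and Igf2, a growth factor, fell by 0.74 ± 0.10, from 487 ± 65.3 FPKM to 321 ± 0.541 and 263 ± 12.6. Both also stand in the list of the imprinted gene network, in which 6 of 15 members were lower and 2 higher (the same counts adjusted over the list alone; camera adjusted p = 0.00333, and adjusted p = 0.166 with an estimated correlation). A member that rose there was decorin, Dcn, by 1.09 ± 0.12.

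Matrix and fibroblast markers moved in both directions, while smooth muscle and cardiac genes had only lower calls when adjusted over all genes. In the list of extracellular matrix and fibroblast markers 12 of 33 members were lower and 5 higher (12 and 6 adjusted over the list alone; camera adjusted p = 0.00333, and adjusted p = 0.576 with an estimated correlation). Dcn, S100a4 (0.72 ± 0.11) and vimentin, Vim (0.68 ± 0.11), were higher, as was Thbs2, a matricellular protein (0.64 ± 0.10), while the lower members reached -0.69. Myotubes also make matrix proteins, so the list is not specific to fibroblasts. Smooth muscle markers were lower in 7 of 10, among them Notch3 and Acta2 (8 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.000131, and adjusted p = 0.147 with an estimated correlation). Cardiac genes were lower in 4 of 10, including Actc1 and Myh7 (the same count adjusted over the list alone; camera adjusted p = 0.002, and adjusted p = 0.225 with an estimated correlation). Actc1, Myh7 and other cardiac members also stand in the sarcomere list, as does Des of the smooth muscle list, so neither list is separate from it. Of the Notch pathway 5 of 13 members were lower and 2 higher, or 7 and 0 under either scaling, with Notch3 at -0.89 ± 0.11, Heyl at -0.93 ± 0.14 and Hes1 at 0.33 ± 0.10 (the same counts adjusted over the list alone; camera adjusted p = 0.00507, and adjusted p = 0.285 with an estimated correlation).

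Of 16 lists that passed for the mean of both arms 14 were lower and 2 higher, where glycolysis and ER stress were lower through GAP-2/3 alone. In the heat shock and oxidative stress list, whose median lay 0.25 above that of all genes, 11 of 18 members were higher and none lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.000902, and adjusted p = 0.147 with an estimated correlation). With the libraries scaled to one median 8 were higher and 1 lower, and under quantile normalization 10 and 1. For GAP-2/3 alone 11 higher and 1 lower became 5 and 1 with one median and 6 and 2 under quantile normalization. Nqo1, a quinone reductase, went from 6.12 ± 0.712 FPKM to 36.8 ± 1.72 and 31.6 ± 0.676. Gclc, which makes the precursor of glutathione, rose by 0.83 ± 0.10, and the metallothionein Mt1 by 1.60 ± 0.19. In the interferon and innate response list 9 of 17 were higher and 2 lower (the same counts adjusted over the list alone; camera adjusted p = 0.00417, and adjusted p = 0.454 with an estimated correlation). Its members Gbp2, Zbp1 and Ccl2 rose by 1.82 ± 0.11, 1.59 ± 0.10 and 1.58 ± 0.11. The rise of Gbp2 came mainly through GAP-2/3, at 3.12 against GAP-scr and 2.60 against GAP-2. Of 23 genes of the p53 and DNA damage response 9 were higher, including Perp, Trp53inp1 and Mdm2, and 1 lower (10 and 1 adjusted over the list alone), but the list did not pass (camera adjusted p = 0.118).

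Under the rule for named genes, with a mean of at least 5 FPKM, the genes with the highest log2 changes over both arms were C130074G19Rik (3.19 ± 0.10), Cd24a (2.82 ± 0.09), Perp (2.81 ± 0.11), Enpp2 (2.69 ± 0.13), Slc16a4 (2.59 ± 0.10), Prr9 (2.47 ± 0.11), Bglap2 (2.44 ± 0.11), Nqo1 (2.30 ± 0.10), S100b (2.24 ± 0.15), Il33 (2.20 ± 0.11), Qpct (2.19 ± 0.13) and Stra6 (2.17 ± 0.14). Cd24a, a surface glycoprotein, stood at 6.36 ± 0.228 FPKM in GAP-scr, 68.5 ± 0.789 in GAP-2 and 38.1 ± 0.0424 in GAP-2/3. Bglap2 shares near-identical sequence with its neighbours Bglap and Bglap3, so its reads cannot be assigned with certainty. Besides Actn2, Cdkn1c, Ryr1, Neb, Acta1, Mfap4 and Heyl, the lowest 12 held Ankrd2 (-1.19 ± 0.19), Slc7a5 (-1.15 ± 0.10), Popdc2 (-1.03 ± 0.20), Hspg2 (-0.97 ± 0.10) and Galnt6, from 31.0 ± 11.4 to 18.4 ± 1.94 and 11.3 ± 0.587 FPKM. Mfap4, a microfibril protein, fell by 1.07 ± 0.21. The largest adjusted p among these 24 genes was 0.00336, for Popdc2.

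In total 3750 of 10993 genes passed an adjusted p of 0.05 for the mean of both arms, 2698 higher and 1052 lower, of which 136 and 11 changed more than 2-fold on this scale. The median log2 change of all genes was 0.10 (0.07 in GAP-2 and 0.13 in GAP-2/3), and with the libraries scaled to one median the split became 1569 higher and 1560 lower, so the excess of higher genes depended on the scaling. No named gene that passed turned its sign under either scaling. The count was 2080 without GAP-2/3 replicate A and 2218 without GAP-2 replicate B.

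**Figure D2:**
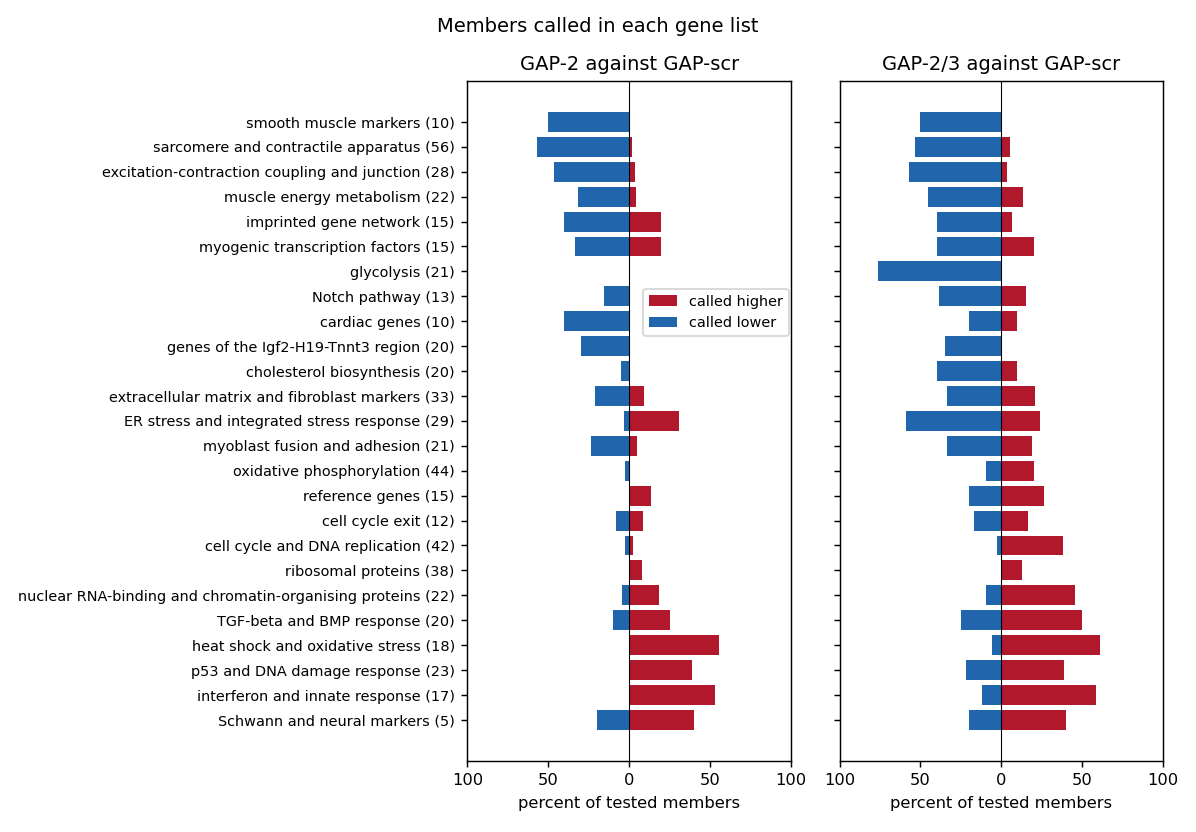
Percent of the tested members of each gene list called higher (red, to the right) or lower (blue, to the left) in GAP-2 and in GAP-2/3 against GAP-scr, with the number tested in brackets. The sarcomere list had 32 of 56 members lower in GAP-2 and 30 in GAP-2/3, and the glycolysis list 0 of 21 and 16.

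The next comparison took each gapmer treatment alone. GAP-2 lowered sarcomere genes and raised stress genes. Against GAP-scr 32 of 56 sarcomere genes were lower and 1 higher (42 and 2 adjusted over the list alone; camera adjusted p = 3.61e-20, and adjusted p = 0.0935 with an estimated correlation). Higher genes included 9 of the 23 of the p53 list, with none lower (12 and 0 adjusted over the list alone; camera adjusted p = 9.33e-05, and adjusted p = 0.455 with an estimated correlation), and 9 of the 29 of the ER stress and integrated stress response list, with 1 lower (11 and 2 adjusted over the list alone; camera adjusted p = 0.0353, and adjusted p = 0.567 with an estimated correlation). With the libraries scaled to one median 4 of its members were higher. The ER stress list did not pass for GAP-2 without GAP-scr replicate A, without GAP-2 replicate B or with a minimum mean of 5 FPKM. Perp, a membrane protein induced by p53, went from 0.608 ± 0.201 to 10.6 ± 0.134 FPKM and Trp53inp1 from 28.3 ± 10.8 to 73.7 ± 6.55. Under the rule for named genes, with a mean of at least 5 FPKM, the 5 highest log2 changes were those of Cd24a (3.24 ± 0.10), C130074G19Rik (3.23 ± 0.12), Perp (2.85 ± 0.13), Bglap2 (2.50 ± 0.12) and Qpct (2.45 ± 0.15). The 5 lowest under this rule were those of Acta1 (-1.04 ± 0.12), Ctgf (-1.03 ± 0.21), Sema7a (-0.99 ± 0.12), Ankrd2 (-0.99 ± 0.22) and Neb (-0.98 ± 0.17). Ankrd2 did not pass without GAP-scr replicate A, at -0.53.

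With GAP-2, 1604 genes passed, 1144 higher and 460 lower, against 686 and 642 after scaling to one median, and 18 lists passed, 5 higher and 13 lower. The count of genes was 504 without GAP-2 replicate B, 592 without GAP-2 replicate A, 943 and 942 without GAP-2/3 replicates A and B, and 2624 without GAP-scr replicate A.

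GAP-2/3 lowered sarcomere genes too and, in addition, genes of glycolysis and of the integrated stress response. Of 56 sarcomere genes 30 were lower and 3 higher (33 and 3 adjusted over the list alone; camera adjusted p = 1.4e-11, and adjusted p = 0.137 with an estimated correlation). Of 21 genes in the glycolysis list, with a median 0.58 below that of all genes, 16 were lower and none higher (the same counts adjusted over the list alone; camera adjusted p = 5.56e-11, and adjusted p = 0.24 with an estimated correlation). Hexokinase 2, Hk2, went from 22.1 ± 1.31 to 9.70 ± 0.277 FPKM, and Vegfa and Car9, hypoxia-induced genes that the list also holds, from 112 ± 8.10 to 58.7 ± 1.35 and from 6.63 ± 0.785 to 2.32 ± 0.772. In the ER stress and integrated stress response list 17 of 29 members were lower and 7 higher (17 and 8 adjusted over the list alone; camera adjusted p = 3.55e-06, and adjusted p = 0.26 with an estimated correlation). Shmt2, a mitochondrial enzyme of serine metabolism, fell by 1.37 ± 0.12, Fgf21 by 1.59 ± 0.18 and Chac1 by 1.49 ± 0.14. In the p53 list 9 of 23 members were higher and 5 lower (the same counts adjusted over the list alone), and the list did not pass (camera adjusted p = 0.893). With the libraries scaled to one median 6 were higher and 7 lower. Of 20 genes in the cholesterol biosynthesis list 8 were lower and 2 higher, the lower ones including Dhcr7 and Mvd (9 and 2 adjusted over the list alone; camera adjusted p = 2.34e-05, and adjusted p = 0.183 with an estimated correlation).

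Under the same rule for named genes, the 5 highest log2 changes with GAP-2/3 were those of S100b (3.51 ± 0.17), C130074G19Rik (3.16 ± 0.12), Enpp2 (2.98 ± 0.15), Slc16a4 (2.96 ± 0.12) and the cytokine gene Il33 (2.83 ± 0.13). The 5 lowest were those of the amino acid transporter Slc7a5 (-1.83 ± 0.12), Fgf21, Actn2 (-1.58 ± 0.14), Cdkn1c (-1.52 ± 0.13) and Adm2 (-1.50 ± 0.17). In all, 4323 genes passed, 3081 higher and 1242 lower, against 1888 and 1817 after scaling to one median, and 16 lists passed, 2 higher and 14 lower. The count of genes was 1538 without GAP-2/3 replicate A. Scaling to one median also cut the higher members of the sarcomere, ER stress and cholesterol lists with GAP-2/3 to 1, 4 and 0.

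The 2 arms were then compared with each other. The changes ran largely together: 928 genes were higher and 314 lower in both arms against GAP-scr, 77.4% of the genes called with GAP-2. Unchanged arms simulated against the same controls gave 0.31 and 0.4 such genes on average, and independent lists of these sizes would share 321 and 52.0. Each gene was simulated independently, so the simulation cannot show what deviations shared by many genes would give. Across genes, which are not independent replicates, the log2 changes of the arms correlated at Pearson r = 0.687 and Spearman rho = 0.713, where simulated unchanged arms gave 0.502 and 0.480. The covariance was 0.0934, against 0.0093 in the simulation. Both arms use the same 2 GAP-scr libraries, too few to split, so part of the overlap may come from these. The names also allow that GAP-2/3 includes the GAP-2 gapmer, so the arms may not be independent reagents. An effect of a shared gapmer beyond Charme would appear in both arms and was not tested. The overlap was 375 genes without GAP-2 replicate B, 472 without GAP-2 replicate A, 525 and 666 without GAP-2/3 replicates A and B, and 1978 without GAP-scr replicate A.

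**Figure D3:**
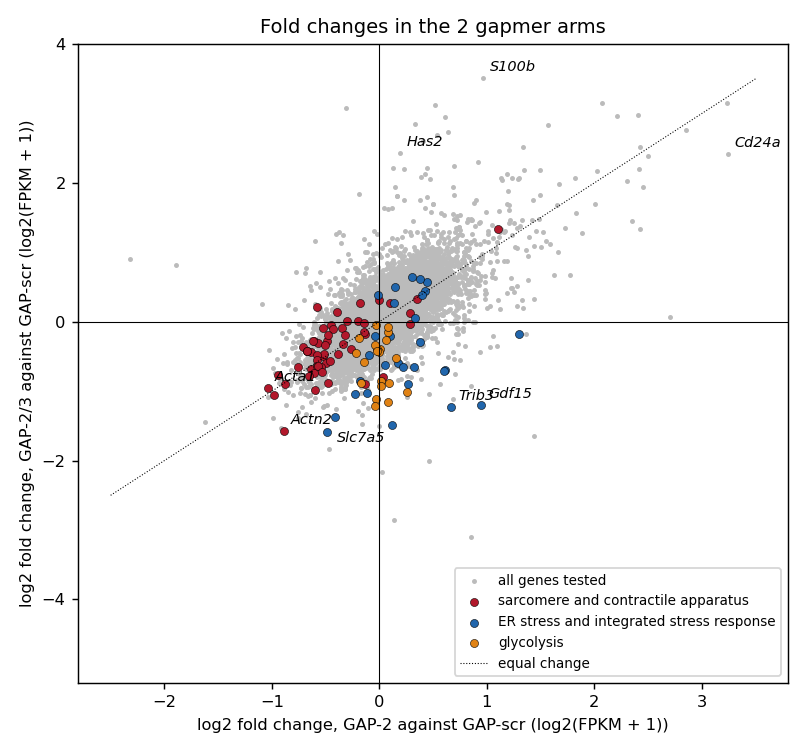
Log2 fold change of each gene with GAP-2 (x axis) and GAP-2/3 (y axis) against GAP-scr, on the log2(FPKM + 1) scale, with members of 3 lists in colour and the dotted line marking equal change. Sarcomere genes lie low on both axes (medians -0.51 and -0.40), while glycolysis genes lie near 0 for GAP-2 and low for GAP-2/3 (medians -0.01 and -0.45).

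Tested against each other, GAP-2/3 and GAP-2 differed at 1115 genes, 714 higher and 401 lower with GAP-2/3 (476 and 436 after scaling to one median). The ER stress and integrated stress response list had 17 of 29 members lower and 1 higher (19 and 3 adjusted over the list alone; camera adjusted p = 1.77e-14, and adjusted p = 0.533 with an estimated correlation). Glycolysis had 9 of 21 lower (16 adjusted over the list alone; camera adjusted p = 1.77e-14, and adjusted p = 0.58 with an estimated correlation). The cell cycle and DNA replication list had 12 of 42 members higher and none lower, with 8 higher after scaling to one median and 7 after quantile normalization (16 and 0 adjusted over the list alone; camera adjusted p = 1.07e-06, and adjusted p = 0.628 with an estimated correlation). The sarcomere list, with 3 members lower and 1 higher (the same counts adjusted over the list alone), did not pass (camera adjusted p = 0.669). In all 5 lists passed, 1 higher and 4 lower with GAP-2/3.

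Individual genes set the arms further apart. Gdf15, a stress-induced cytokine, stood at 10.7 ± 0.859 FPKM in GAP-scr, 21.5 ± 1.84 in GAP-2 and 4.11 ± 0.416 in GAP-2/3. Trib3, Ndrg1 and Ero1l likewise rose with GAP-2 and fell with GAP-2/3. Has2, which makes hyaluronan, was at 12.8 ± 0.361 and 14.8 ± 1.03 FPKM in GAP-scr and GAP-2 and at 73.3 ± 3.35 in GAP-2/3, and S100b, Krt19, Slc2a3 and Ednra were also higher with GAP-2/3. Amd1 passed with the largest fall among the named genes (-3.09 ± 0.87), but its libraries spread widely and it has a near-identical copy, Amd2, so its reads cannot be assigned with certainty. It did not pass after scaling to one median (-3.13) or by quantiles (-3.11), or with a pseudocount of 0.1, where the change was no smaller than in the main analysis. Without GAP-2/3 replicate A the change shrank to -1.21 and did not pass. The count of 1115 fell to 195 and 243 without GAP-2/3 replicates A and B and to 351 and 533 without GAP-2 replicates A and B. It rose to 2038 and 2052 without GAP-scr replicates A and B.

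The ChIRP-seq data addressed where on the genome Charme was found. The authors' merged list held 798 peaks with 1 score each and no values per pull-down, so the even and odd probes could not be compared, nor set against LacZ or input here. The submitters' processing notes name mm9, but the last peak on chromosome X ends at 170732078, beyond the end of that chromosome in mm9 (known in general, not from a file used here), and the positions fit GRCm38. They were therefore read as GRCm38 and set beside the spans of RefSeq genes of that assembly (GRCm38.p6), which carry no exons or introns here. The build rests on this reading. The 2 peaks on chromosome 7 and the widest peak described next were chosen after their values were seen.

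The peak widths ran from 82 to 858 bp with a median of 105 bp, and 311 peaks (39.0%) were 82 or 83 bp wide. On the nuclear chromosomes 428 of 793 peaks (54.0%, exact 95% binomial interval 50.4 to 57.5%) overlapped a RefSeq gene span, where such spans cover 47.2% of the length up to the last gene of each chromosome. The second-widest peak, chromosome 7: 44484821 to 44485453 (633 bp, score 2474), lay on the lncRNA gene 5430431A17Rik, overlapping its span by 593 bp, with Emc10 4484 bp away. No source used here gives the position of Charme, but from general knowledge this gene may be Charme's own, and probes can capture the DNA of their target's locus directly. The peak therefore does not show binding away from that locus. A peak at chromosome 7: 142560946 to 142561128 (183 bp, score 3279) lay between 2 lncRNA genes, 2348 bp from Nctc1 and 14402 bp from H19. The widest peak, chromosome 2: 98666446 to 98667303, had a score of 96.8.

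The highest score was shared by 13 peaks. Of these, 6 lay in the span of a protein-coding gene, Nav1 (chromosome 1: 135578271 to 135578428), Fbxo25 (chromosome 8: 13923746 to 13923902), Ankrd6 (chromosome 4: 32897253 to 32897403), Sema3a (chromosome 5: 13331396 to 13331528), Plcl2 (chromosome 17: 50530096 to 50530178) and Fer (chromosome 17: 64109621 to 64109703). The other 7 lay outside gene spans, the widest of them, chromosome 1: 167671496 to 167671773, at 16457 bp from Lmx1a.

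**Figure D4:**
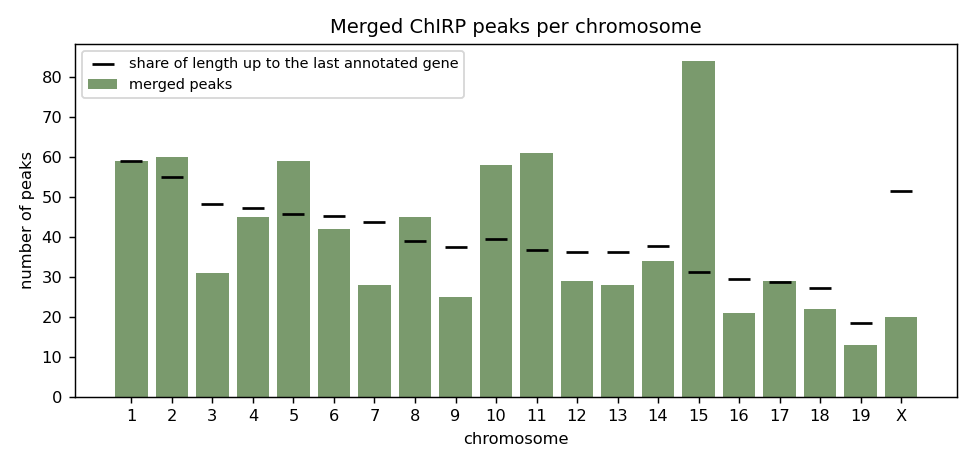
Number of merged ChIRP peaks per nuclear chromosome (bars) beside the number that the chromosome's share of length would give (dashes), where the length runs to the last annotated gene. Chromosome 15 held 84 peaks against 31.3 by length, and chromosome X 20 against 51.4.

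Genes under peaks were compared with genes that changed in the mean of both arms. Of 10950 tested genes with a RefSeq span 191 overlapped a peak, and 74 of these had changed (38.7%), against 34.0% of the genes without a peak. The odds ratio was 1.23 (95% interval 0.90 to 1.66, two-sided Fisher's exact test p = 0.19). Split by direction, which was done after the data were seen, 37 of the 191 were lower (19.4%, against 9.39% of the others; odds ratio 2.32, 1.57 to 3.36, exact p = 2.88e-05) and 37 were higher (19.4%, against 24.6%; odds ratio 0.74, 0.50 to 1.06, exact p = 0.107). Genes with a peak were longer, with a median span of 103412 bp against 22511 bp. With log10 span as a covariate the odds ratio for lower genes was 1.69 (1.16 to 2.45).

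The changed genes under peaks with the smallest p were Cobll1 (1.30 ± 0.12), Rptor, the scaffold of the mTORC1 kinase complex (-0.80 ± 0.10), the guidance cue Sema3a (0.71 ± 0.10), Fbxo25 (0.65 ± 0.09), the insulin receptor substrate Irs1 (0.70 ± 0.10), Trio (-0.70 ± 0.10), Maml3 (-0.69 ± 0.10), nucleophosmin, Npm1 (0.63 ± 0.10, with processed pseudogenes that may share its reads), Robo2 (0.70 ± 0.11) and Ttc28 (-0.63 ± 0.10). Rptor went from 34.0 to 22.4 and 16.4 FPKM with a peak at chromosome 11: 119654996 to 119655078, and Irs1 from 14.3 to 19.6 and 28.6 with a peak at chromosome 1: 82273921 to 82274002. Sema3a and Fbxo25 were under peaks with the highest score.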

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

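The results here were picked out because the effects of the 2 gapmer treatments differed by a test of the difference itself. Of the tests below, those of the matrix markers and of a single response with 2 strengths were chosen after the results were seen, and so was the split of the peak comparison by direction, also with one median.

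GAP-2/3 and GAP-2 differed at 1115 genes, and camera set apart the lists of glycolysis (adjusted p = 1.77e-14), ER stress and integrated stress response (adjusted p = 1.77e-14), cell cycle and DNA replication (adjusted p = 1.07e-06), p53 and DNA damage response (adjusted p = 1.54e-05) and cholesterol biosynthesis (adjusted p = 9.6e-05). With an estimated correlation the adjusted p was 0.58, 0.533, 0.628, 0.628 and 0.533 in that order. The cell cycle list was higher with GAP-2/3 and the other 4 lower. Of the 23 members of the p53 list 1 was called higher and 4 lower. Among named genes, log2 differences (GAP-2/3 minus GAP-2) were 2.54 for S100b, 2.24 for Has2, 2.10 for Krt19, 2.09 for Slc2a3 and 2.03 for Ednra, and -3.09 for Amd1, -2.14 for Gdf15, -1.90 for Trib3, -1.80 for Ndrg1 and -1.78 for Ero1l.

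Genes of the ER stress list moved apart between the arms. A single response that was only stronger in one arm would leave no gene with opposite calls, yet 5 of the 29 members of the ER stress list, Atf3, Trib3, Psat1, Vldlr and Gdf15, were higher with GAP-2 and lower with GAP-2/3. The list was picked because the arms differed in it, so this count is not set against a random list. A single library standing apart is also argued against: the list's median difference of -0.68 stayed between -0.61 and -0.85 when each of the 4 gapmer libraries was left out (nearest to 0, -0.612). An effect of one oligonucleotide beyond Charme, a difference in knock-down between arms and a difference between the cultures (medium, density) stay open, since the culture of each library is not given and Charme was not measured here.

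The fall of sarcomere and excitation-contraction genes in both arms was set against 2 technical explanations. For a lower share of myotubes, the extracellular matrix and fibroblast list was examined. In it 12 members were lower and 5 higher, from -0.69 to 1.09 (Dcn) on the log2 scale. This test cannot decide, since the list does not mark unfused myoblasts and myotubes also make matrix proteins. Myf5, a factor of undifferentiated myoblasts, rose in both arms, whereas Myod1 fell. Genomic span, introns included, is argued against. After the median of genes of like span was taken off, the median log2 change of the 84 members was -0.526, and before it, relative to all genes, -0.541. Across all genes span and change correlated at only Spearman rho = -0.0467. The bootstrap 95% interval of -0.60 to -0.46 resampled genes and not libraries. It therefore ignores the correlation of these genes and the spread between libraries. Transcript length, to which FPKM is scaled, was not tested. Fewer or less mature myotubes stay open, with or without a change in the matrix genes. An effect of the knock-down on muscle genes stays an untested hypothesis, as does an effect beyond Charme of a gapmer that both arms may share.

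Genes under ChIRP peaks were more often lower (odds ratio 2.32). Genes with a peak are longer, and with log10 span as a covariate the odds ratio was 1.687 (95% interval 1.159 to 2.454), and 1.661 (1.14 to 2.419) with expression level as well. The interval stays above 1 but not above the bound of 1.2 set before this ratio was computed, so length and an effect at peaks cannot be told apart. With the libraries scaled to one median the uncorrected odds ratio was 2.00 (1.40 to 2.82). Occupancy by Charme remains an untested alternative, since no values per pull-down were used.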

How the results depend on the processing

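The fits without both libraries highest in Rn45s and the peak comparisons by direction were chosen after the data were seen. Each result was recomputed under the alternatives, and in those that leave an arm with 1 library, that library is assumed to vary like the others. The counts of genes stayed within 1.5 times for a pseudocount of 0.1, both filters, both scalings, no intensity trend and without both libraries highest in Rn45s. At a threshold of 0.1 there were 2567 genes for GAP-2, 1781 between the arms and 2013 in both arms the same way. With only the 4 libraries of the groups compared there were 937 for GAP-2 and 2055 between the arms, where the spread comes from fewer libraries.

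Leaving out 1 library gave 504 (GAP-2 replicate B) to 2624 (GAP-scr replicate A) genes for GAP-2, 1538 (GAP-2/3 replicate A) to 4481 for GAP-2/3, 2080 (GAP-2/3 replicate A) to 3948 for both arms, 195 (GAP-2/3 replicate A) to 2052 (GAP-scr replicate B) between the arms and 375 (GAP-2 replicate B) to 1978 (GAP-scr replicate A) in both arms the same way, where the cause beyond fewer libraries was not tested. The comparison between the arms uses the GAP-scr libraries only through the shared estimate of the spread, so its rise without 1 of them comes from that estimate. The replicates of GAP-scr differed most, by a median absolute log2 difference of 0.16, against 0.09 in GAP-2 and 0.13 in GAP-2/3. The other libraries that moved a count are named with the comparisons in the report. The correlation of the arms ran from 0.614 (GAP-2 replicate B) to 0.727 (GAP-scr replicate B), and was 0.736 without both libraries highest in Rn45s, where the cause was not tested. Over the settings tried for lists with the preset correlation, those past the threshold numbered 15 to 18, 13 to 17 and 15 to 18. These counts are for GAP-2, GAP-2/3 and both arms. The 17 was reached with a minimum mean of 5 FPKM and without both libraries highest in Rn45s. With an estimated correlation the lists past the threshold numbered 0, 0 and 0. With fry, which does not compare a list with other genes, they numbered 6 for GAP-2, 15 for GAP-2/3 and 9 for both arms. Against GAP-scr the sarcomere list passed in each alternative tried for lists except the estimated correlation. Lists that lost the call for both arms under other camera settings were ER stress (quantiles, without GAP-2 replicate A, without GAP-scr replicate B) and myogenic factors (without both libraries highest in Rn45s). For GAP-2, the lists of ER stress and cell cycle lost it with a minimum mean of 5 FPKM, where the cell cycle list turned from lower to higher, that of ribosomal proteins with the replicate block, and 5, 3, 3 and 3 lists without GAP-scr replicate A, GAP-2 replicate A, GAP-scr replicate B and GAP-2 replicate B. These were ER stress, cell cycle, ribosomal, myogenic factors, imprinted network, cholesterol, Notch and interferon, and 4 of them (myogenic factors, imprinted network, cholesterol, ribosomal) were lost without both libraries highest in Rn45s. For GAP-2/3, fusion, matrix and cardiac lists lost it under quantile normalization and, with interferon, without GAP-scr replicate B. Matrix was also lost without GAP-2/3 replicate A, heat shock and cardiac without GAP-2/3 replicate B, and myogenic factors without GAP-scr replicate A or both libraries highest in Rn45s.

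The scalings moved the direction of calls: for both arms 1568 genes were higher and 1695 lower under quantile normalization, for GAP-2 692 and 687, for GAP-2/3 1820 and 1960, and between the arms 493 and 503. The lists of oxidative phosphorylation and reference genes turned the sign of their medians for both arms under a scaling, and the cell cycle list did under quantile normalization (0.13 to -0.01). No named gene that passed turned its sign, and 5 of 486 checks of these genes lost the call, 4 of them for Amd1.

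With the letters A and B as a replicate block, 1955 genes passed for GAP-2, 4466 for GAP-2/3, 3944 for both arms, 1469 between the arms and 1466 the same way in both arms. The letters do not show pairing across all groups. Deviations from the group means correlated at 0.36 between GAP-scr and GAP-2, -0.13 between GAP-scr and GAP-2/3 and -0.18 between GAP-2 and GAP-2/3. The A libraries of GAP-scr and GAP-2 were also those highest in Rn45s. Whether they share a step of preparation was not tested.

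Of the peaks 383 had a score above the median and 2 were at least 500 bp wide. The odds ratio of changed genes under a peak was 1.13 and 1.06 with spans extended by 10 and 50 kb and 1.01 for the higher-scoring peaks, and with only lower genes 2.32 (1.69 with length, 1.66 with length and level, 2.00 with one median), against 0.735 with only higher genes, where the cause was not tested. The alternatives for Charme in each library and the count-based tests were not run. Depth limits all of this to an unknown extent, as FPKM values do not retain it.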

Other observations

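The genes here were chosen after their values were seen, except where a list is named, and none of them is tested as an explanation.

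Aldh3a1, an aldehyde dehydrogenase, stood at 2.28 ± 0.0767 FPKM in GAP-scr, 16.6 ± 0.976 in GAP-2 and 7.30 ± 1.28 in GAP-2/3 (SD, n = 2). Mgst1, a microsomal glutathione transferase, went from 2.05 ± 0.718 to 9.70 ± 0.523 and 7.87 ± 0.132, and Srxn1, sulfiredoxin, from 7.95 ± 0.592 to 19.4 ± 0.161 and 10.9 ± 0.571. Gclm, the partner of Gclc, rose from 4.33 ± 0.882 to 6.43 ± 0.227 and 6.36 ± 0.223. Hmox1, heme oxygenase 1, was at 44.5 ± 4.07, 73.8 ± 4.38 and 44.2 ± 1.31 FPKM.

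RNA-binding proteins of the nucleus held 9 higher and 2 lower members of 22 for both arms (10 and 2 adjusted over the list alone), though camera did not pass (adjusted p = 0.515). Ptbp2, a splicing regulator, went from 8.24 ± 0.410 FPKM to 11.6 ± 1.11 and 30.9 ± 1.36, Mbnl1 from 44.8 ± 3.91 to 66.2 ± 4.89 and 94.9 ± 6.06, and Matr3, matrin 3, rose by 0.54 ± 0.12 on the log2 scale. In the TGF-beta and BMP list 9 of 20 members were higher and 5 lower (the same counts adjusted over the list alone; camera adjusted p = 0.712), with Bmp4 at 1.13 ± 0.161, 3.95 ± 0.364 and 4.85 ± 0.159 FPKM. Ccnd1, cyclin D1, went from 16.3 ± 2.18 to 38.9 ± 1.16 and 45.4 ± 3.23 FPKM in a cell cycle list that did not pass for both arms (7 of 42 higher and 2 lower, but 4 and 8 under quantile normalization; 6 and 1 adjusted over the list alone; camera adjusted p = 0.848).

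A further 5 lists did not pass for both arms. Oxidative phosphorylation had 4 higher and 4 lower of 44 (1 and 1 adjusted over the list alone; camera adjusted p = 0.53) and ribosomal proteins, which have many pseudogenes, 6 and 0 of 38, but 2 higher with one median (5 and 0 adjusted over the list alone; camera adjusted p = 0.231). Cell cycle exit had 2 and 1 of 12 (1 and 1 adjusted over the list alone; camera adjusted p = 0.602). Schwann and neural markers had 3 and 1 of 5 (camera adjusted p = 0.477) and reference genes 5 and 2 of 15 (camera adjusted p = 0.907), both with the same counts adjusted over the list alone. The medians of the oxidative phosphorylation, cell cycle exit and reference lists were above 0 (0.05, 0.10 and 0.08) while camera ranked all 3 as lower than other genes, and the mean of the cell cycle exit list was below 0. Under a scaling the medians of the oxidative phosphorylation and reference lists fell below 0, and with one median their counts were 1 higher and 5 lower, and 2 and 2. Of the 2 macrophage markers tested, Cd68 was at 0.645 ± 0.384, 2.99 ± 0.785 and 0.898 ± 0.0900 FPKM and Cd14 at 2.94 ± 0.269, 4.50 ± 0.492 and 4.50 ± 0.123. Of the 3 adipocyte markers, Cebpa alone passed for the mean of both arms, carried by GAP-2/3: 1.15 ± 0.311 FPKM in GAP-scr, 0.995 ± 0.156 in GAP-2 and 3.66 ± 0.881 in GAP-2/3.

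The 3 lists left passed as lower in the mean of both arms, although ER stress passed as higher with GAP-2 alone (9 higher and 1 lower) and glycolysis had no call there: ER stress with 6 higher and 6 lower of 29 (7 and 9 adjusted over the list alone; camera adjusted p = 0.0254, and adjusted p = 0.597 with an estimated correlation), glycolysis with 0 and 8 of 21 (0 and 10 adjusted over the list alone; camera adjusted p = 7.53e-07, and adjusted p = 0.324 with an estimated correlation) and cholesterol biosynthesis with 1 and 7 of 20 (2 and 7 adjusted over the list alone; camera adjusted p = 0.000335, and adjusted p = 0.166 with an estimated correlation). The ER stress call was lost under quantile normalization and without GAP-2 replicate A or GAP-scr replicate B.

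Hba-a1, an α-globin gene with a near-identical copy, stood at 4.26 ± 0.603 FPKM in GAP-scr, 0.0511 ± 0.0713 in GAP-2 and 8.81 ± 0.822 in GAP-2/3, and is 1 of the 28 genes called in opposite directions in the arms. Its log2 change with GAP-2 (-2.32) was lower than those ranked above, where a mean of at least 5 FPKM was required.

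The peak scores were not spread evenly. Of 798 peaks 490 (61.4%) shared their score with another peak, and 150 had a score at a whole multiple, from 2 upwards, of the highest score divided by 15 (tolerance 0.002 of that step). Of the 18 peaks with a score under 150, 17 lay on the mitochondrial chromosome (5 peaks, 49.2 to 63.7), in a cluster on chromosome 2 (98662223 to 98667303), in a cluster on chromosome 14 (19416171 to 19418502) or in the first 4 Mb of chromosome 9. By length up to the last gene, 6 of 20 chromosomes departed from their share at an adjusted p under 0.05, with 10, 11 and 15 above it and 3, 7 and X below: chromosome 15 held 2.68 times the number of peaks (84, exact binomial test, adjusted p = 1.66e-14 over 20 chromosomes), chromosome 11 held 1.66 times (61, adjusted p = 0.00119) and chromosome X 0.389 times (20, adjusted p = 5.2e-06). The test takes peaks as independent and spread evenly by length, though some lie close together. Input and LacZ were not used, so a preference of Charme cannot be told apart from uneven representation of the chromosomes in the sequenced DNA.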
